A study of Homo sapiens with 4 samples.

How the data were processed

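The series holds 4 RNA libraries of the human breast cancer cell line MDA-MB-231, 2 from cells kept with the solvent DMSO and 2 from cells kept with RB-1 for 24 h. Per the labels' protocols, libraries were prepared from total RNA with an mRNA library kit. The deposited table holds raw counts per gene, not normalised, for 20263 human Ensembl gene IDs, 1 column per library, with no pooling. The aligner, the counting tool, their settings and the use of strand are not given in the sources used here. The genome builds listed in the submitters' processing notes, GRCm38 and mm10, are those of the mouse, while every ID in the table is human, so the build behind the counts is not settled and no coordinates are printed. Symbols came from a table of human gene names, which matched 20148 of the IDs. Where a read falls on genes that overlap or join their neighbours, the counting decides which gene receives it, so named genes that share many exon bases with another gene are marked as uncertain where they are described. Smaller shares, the largest being 9.1% for CCNA2, are not marked.

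Library totals ran from 34122874 to 37754168 counts. Replicate libraries were compared first: over genes with a mean of at least 10 counts, the chi-square per degree of freedom was 255.3 between the DMSO libraries and 127.4 between the RB-1 libraries, far above sampling noise, so all were kept as separate samples. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 13612. TMM factors ran from 0.868 to 1.10, and RB-1 was compared with DMSO by edgeR's quasi-likelihood F test (estimateDisp, glmQLFit with robust estimation, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene before the spread was shared across genes, and its common biological coefficient of variation was 0.251. The standard error of a log2 fold change is its size divided by the square root of F (median 0.307). CPM values are counts scaled to the TMM library sizes. A fold against a group at 0 counts is a lower bound, taken against a floor of 3 counts over that group, and covers counting error only.

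Fixed before the data were examined were 23 gene lists with 586 members, all of them found in the table. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation in place of the preset one, 0 of the 13 lists that passed remained past the threshold, the smallest adjusted p was 0.332, and 3 of the 23 lists had an unadjusted p under 0.05. That version also judges each list on the 2 residual degrees of freedom, so the correlation alone does not account for the losses. The interferon and hypoxia lists had estimated correlations of 0.0047 and -0.0013, below the preset 0.01. Their camera unadjusted p still went from 2.76e-05 and 4.62e-06 to 0.0473 and 0.0366. The rotation test fry, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes, passed 8 lists, and its version for changes in either direction passed 20. Genes named in the text were chosen by a rule set before the data were examined: the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 100 counts and no overlap between the groups, a panel of 13 genes of p53 and the cell cycle whatever their values, the 4 members with the smallest p in each list that passed, and the 1 with the smallest p in each other list. Genes named outside the rule are marked as such, except those named only as the neighbour of another gene or, for CCL20, for its 0 counts in DMSO, and 2 genes that the rule takes are not reported here.

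The fit was tested on simulated counts for the same 13612 genes, in 5 simulations with 200 genes changed and the G2/M and mitosis list lowered 2-fold. With gene-wise dispersions it recovered 1.79% of genes changed 1.5-fold, 16.1% of those changed 2-fold and 82.1% of those changed 4-fold, none with the wrong sign, and 20.0% of its calls were false. With trended dispersions it recovered 2.99%, 18.2% and 86.4%, with 2.94% of calls false. So with 2 libraries per group a gene that does not pass may well have changed by 2-fold, and where genes differ in their own spread the share of false calls can exceed the nominal one. Far fewer genes were changed there than the 3926 called in the data, so the shares recovered and false need not hold for the data. The simulated changed list was called in 5 of 5 simulations and other lists in 0 of 110 tests. Each gene was drawn independently there, so this cannot show how the list test behaves where the genes of a list move together.

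Alternatives fixed beforehand were RLE and upper-quartile factors, library totals alone, no count filter and a stricter one, DESeq2 1.42.0, limma-voom, edgeR's legacy fit, an adjusted p under 0.01, a 2-fold minimum, a test against a 1.5-fold change, the replicate number as a block, each library left out in turn, and the fit without the 20 most abundant and the 13 mitochondrially encoded genes. Chosen after seeing the data were a correction of each library for transcript length and GC content (natural splines with 4 degrees of freedom each, lengths and GC from GENCODE 29 transcripts), the fit without genes whose symbols join a pair of other symbols, and a crossed pairing of the replicate numbers. Genomic spans, chromosomes and shared exon bases were taken from GENCODE 29 by gene ID with Python 3.11.15.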

Results

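RNA was sequenced from MDA-MB-231 cells, an established human cell line derived from a triple-negative breast cancer. The cells had been kept for 24 h with RB-1, which the series title calls a derivative of ribociclib, or with the solvent DMSO. Ribociclib is an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. RB-1 itself is known here by its code name, and the labels give no dose. Each group had 2 libraries, prepared with an mRNA library kit and counted per gene. The library totals were 34774542 and 37754168 counts for DMSO replicates 1 and 2, and 36081265 and 34122874 for RB-1 replicates 1 and 2. The comparison asks which transcripts differ after RB-1, and the title of the series names p53 and the cell cycle as its subjects.

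After RB-1, transcripts of 30 of 46 tested genes of mitosis fell, with the proliferation marker MKI67 8.65-fold lower. Transcripts of many homologous recombination and heat shock genes fell with them. Inflammatory cytokine transcripts rose, IL1B by 20.7-fold and CXCL8 by 11.9-fold. Genes of the amino acid and stress response driven by ATF4 rose, as did genes of glycolysis and hypoxia. The p53 target list did not pass its test, with 10 of its members higher and 5 lower. In total 1737 genes were higher and 2189 lower in RB-1 among 13612 tested, at an adjusted p under 0.05 by edgeR's quasi-likelihood test. Fold changes followed transcript length, with 189 genes higher and 1045 lower in the quartile with the longest transcripts. The RB-1 libraries also differed from each other along length (Spearman 0.399), so these folds may partly reflect the libraries. With a correction for length and GC content the mean log2 fold change of the mitosis list was -0.92, against -1.23. The list tests used a preset correlation between genes. With an estimated correlation, where camera also has only 2 residual degrees of freedom, the smallest adjusted p of any list was 0.332. With the rotation test fry the homologous recombination (adjusted p = 0.0694), apoptosis (0.0684), lysosome (0.0701), NF-kB (0.0523), NRF2 (0.0555) and oxidative phosphorylation (0.213) lists did not pass, and the list of YAP/TEAD targets, which did not pass camera, did (0.0355).

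Of these calls, 1335 higher and 1878 lower genes differed by at least 2-fold. In all 3926 called genes both RB-1 libraries lay beyond both DMSO libraries, which was also the case for 69.7% of all tested genes, where chance gives 33.3%. The balance of directions moved with the scaling: upper-quartile factors gave 2171 higher and 1830 lower genes, and library totals alone gave 2059 higher and 1400 lower, with the median log2 fold change shifted by 0.11 and 0.19. The counts also depended on single libraries, with 768 higher and 1361 lower without DMSO replicate 1, 522 and 1302 without DMSO replicate 2, and 655 and 1065 without RB-1 replicate 1. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

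Genes of mitosis were the list with the smallest p in camera with the preset correlation. With an estimated correlation the hypoxia and glycolysis list had the smallest (camera unadjusted p = 0.0366, against 0.0722 for mitosis). Of 46 G2/M and mitosis genes tested, 30 fell, 3 rose and 13 did not pass (3 higher and 31 lower adjusted over the list alone). The mean log2 fold change was -1.23 (camera adjusted p = 2.74e-14; adjusted p = 0.332 with an estimated correlation). MKI67 (ENSG00000148773) had a normalised expression of 1497 ± 40.0 CPM in DMSO and 173 ± 2.26 in RB-1 (SD, n = 2 each; log2 fold change -3.11 ± 0.23 SE, adjusted p = 9.23e-05). CENPF, a kinetochore protein, was 11.8-fold lower (log2 fold change -3.55 ± 0.28). TOP2A, the topoisomerase that untangles chromosomes, was 7.66-fold lower (-2.94 ± 0.27), and ANLN, a scaffold of the dividing cell's contractile ring, 6.59-fold lower (-2.72 ± 0.25). The 3 members that rose were MAD2L1, a spindle checkpoint protein, PTTG1, the securin that holds back chromosome separation, and CENPA, the centromeric histone, each by a log2 fold change of 0.80 to 1.0; they were chosen for mention after their values were seen. None of the list rose without DMSO replicate 1, DMSO replicate 2 or RB-1 replicate 1, while 25, 27 and 26 fell. CCNB1, the mitotic cyclin B1, differed by less than the error (0.10 ± 0.25, adjusted p = 0.801). CDK1 (0.26) and CCNB2 (0.0048), named after their values were seen, were also among the 13 that did not pass.

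Genes of S phase entry and DNA replication fell in part. In the G1/S and DNA replication list 15 of 46 fell, none rose and 31 did not pass (16 lower adjusted over the list alone), with a mean log2 fold change of -0.55 (camera adjusted p = 0.00146; adjusted p = 0.407 with an estimated correlation). Those that fell numbered 8, 9 and 9 without DMSO replicate 1, DMSO replicate 2 and RB-1 replicate 1, with 1 higher in the last case. It was 9 with library totals alone, and 2 genes were higher without RB-1 replicate 2. CLSPN, an adaptor of the replication checkpoint, was 7.68-fold lower (-2.94 ± 0.30, adjusted p = 0.000282), POLA1, the catalytic subunit of the primase-bound polymerase, 5.95-fold lower (-2.57 ± 0.34), and MCM10, a helicase cofactor, 4.61-fold lower (-2.20 ± 0.32). CDC6, which loads the replicative helicase, was 2.42-fold lower (-1.28 ± 0.24). In the homologous recombination and Fanconi list 14 of 21 fell, none rose and 7 did not pass (15 lower adjusted over the list alone), with a mean of -1.28 (camera adjusted p = 4.92e-07; adjusted p = 0.407 with an estimated correlation). The number that fell was 9 without DMSO replicate 1. RBBP8, which starts the resection of broken ends, was 6.32-fold lower (-2.66 ± 0.27, adjusted p = 0.000303), BRCA1 4.02-fold lower (-2.01 ± 0.29) and the helicases BLM and FANCM 4.52-fold and 5.72-fold lower.

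**Figure D1:**
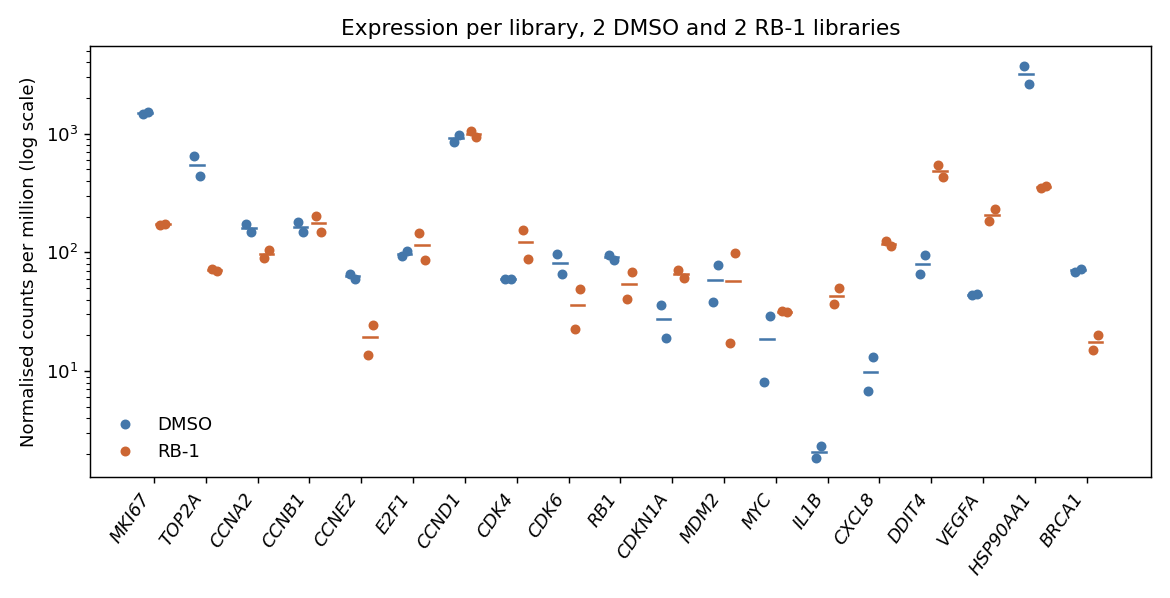
Normalised expression (CPM) on a log axis for 19 genes, with a point for each of the 2 DMSO libraries (blue) and the 2 RB-1 libraries (orange) and a line at each group's mean. MKI67 lies near 1497 in DMSO and 173 in RB-1, and the RB-1 libraries of MDM2 lie far apart, at 17.1 and 98.7.

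The drug targets of ribociclib and the other regulators of the CDK4/6-RB pathway moved in both directions. Of 20 tested, 5 rose, 2 fell and 13 did not pass (the same numbers adjusted over the list alone), and the list did not pass its test (mean log2 fold change 0.13, camera adjusted p = 0.532). The list had 2, 0, 0 and 3 higher and 1, 2, 1 and 3 lower without DMSO replicate 1, DMSO replicate 2, RB-1 replicate 1 and RB-1 replicate 2, and 1 lower with upper-quartile factors, library totals alone or no count filter. CDK4 rose (1.03 ± 0.30, adjusted p = 0.0272) and CDK6 fell (-1.18 ± 0.38, adjusted p = 0.0422). RBL1, the RB relative p107, was 2.67-fold lower (-1.42 ± 0.27, adjusted p = 0.00484), and CCNE2, the S phase cyclin E2, 3.28-fold lower (-1.71 ± 0.33, adjusted p = 0.00485). CCNA2, cyclin A2, was 1.67-fold lower (-0.74 ± 0.24, adjusted p = 0.0416). CCND1 (0.11 ± 0.22, adjusted p = 0.723), E2F1 (0.24 ± 0.29, adjusted p = 0.561), RB1 (-0.74 ± 0.30, adjusted p = 0.0833) and MYC (0.76 ± 0.54, adjusted p = 0.335) did not pass. CCNE2, CCNA2, E2F1 and MYC come from the fixed panel and are not members of this list, in which CDK6 and RBL1 were the 2 that fell. About 43.2% of the exon bases of CDK4 and 37.0% of those of CCNE2 overlap a gene on the opposite strand, and the use of strand in counting is not given in the sources used here, so reads of the neighbours TSPAN31 and INTS8 may be among their counts. CCND1 shares 10.3% with LTO1 in the same way. Several of these calls were lost when 1 library was left out. CDK4 was at 1.03 (adjusted p = 0.102) without DMSO replicate 1, 1.05 (0.112) without DMSO replicate 2 and 0.56 (0.169) without RB-1 replicate 1. CDK6 was at -0.88 (0.208) without DMSO replicate 1 and -0.72 (0.163) without RB-1 replicate 1. CCNA2 was at -0.63 (0.228), -0.82 (0.126) and -0.62 (0.153) without DMSO replicate 1, DMSO replicate 2 and RB-1 replicate 1. CDK6 and CCNA2 also did not pass with upper-quartile factors (-1.06, adjusted p = 0.0650; -0.63, adjusted p = 0.0705), library totals alone (-0.99, adjusted p = 0.102; -0.55, adjusted p = 0.154) or no count filter (adjusted p = 0.0565 and 0.0521). RB1 passed without RB-1 replicate 2 (-1.16, adjusted p = 0.0196), and MYC without DMSO replicate 2 (1.98, adjusted p = 0.0139).

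Targets of p53 also moved both ways. Of 36 tested, 10 rose, 5 fell and 21 did not pass (the same numbers adjusted over the list alone), with a mean log2 fold change of 0.18 (camera adjusted p = 0.226). There were 5, 3 and 6 higher and 4, 3 and 3 lower without DMSO replicate 1, DMSO replicate 2 and RB-1 replicate 1. CDKN1A, which encodes the CDK inhibitor p21, rose 2.37-fold, from 27.7 ± 12.1 to 65.7 ± 7.73 CPM (SD, n = 2 each; 1.25 ± 0.34 SE, adjusted p = 0.0200). Its call was lost without DMSO replicate 2 (0.88, adjusted p = 0.181) and without RB-1 replicate 1 (1.13, adjusted p = 0.104). ASCC3, a DNA helicase subunit, was 5.90-fold lower (-2.56 ± 0.33, adjusted p = 0.000704) and had the smallest p of the list. MDM2, the ubiquitin ligase of p53, had a mean change of -0.02 ± 1.01 (adjusted p = 0.994) with its RB-1 libraries at 17.1 and 98.7 CPM against 38.3 and 78.8 in DMSO. Without RB-1 replicate 2 it was lower (-1.77, adjusted p = 0.0372).

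Regulators of apoptosis rose as a list: 8 of 29 rose, none fell and 21 did not pass (the same numbers adjusted over the list alone), with a mean of 0.71 (camera adjusted p = 0.000596; adjusted p = 0.407 with an estimated correlation). All that rose are named here, also those outside the rule for named genes (BBC3, BAK1, CASP8 and CASP6). Of them, PMAIP1, TNFRSF10B, BAD, BBC3, BAK1, CASP8 and CASP6 promote cell death and MCL1 opposes it. The rises numbered 5, 3 and 4 without DMSO replicate 1, DMSO replicate 2 and RB-1 replicate 1, and 2 genes fell without RB-1 replicate 2. PMAIP1, which encodes the death-promoting protein NOXA, was 2.93-fold higher (1.55 ± 0.26, adjusted p = 0.00257) and the death receptor gene TNFRSF10B 2.33-fold higher (1.22 ± 0.23). BAD, uncertain because 23.7% of its exon bases overlap GPR137 on the opposite strand, was 3.0-fold higher (1.59 ± 0.33), and MCL1 2.08-fold higher (1.06 ± 0.23). Without DMSO replicate 2, BAD (1.36, adjusted p = 0.0648) and MCL1 (0.97, adjusted p = 0.0623) did not pass.

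Inflammatory transcripts gave the list with the largest mean rise. Of 25 NF-kB and inflammatory genes, 14 rose, none fell and 11 did not pass (16 higher adjusted over the list alone), with a median log2 fold change of 1.24, also when CCL20, at 0 counts in both DMSO libraries, is set to its lower bound (camera adjusted p = 2.08e-08; adjusted p = 0.407 with an estimated correlation). The rises numbered 8 and 9 without DMSO replicate 1 and RB-1 replicate 1. IL1B (ENSG00000125538), the cytokine interleukin-1 beta, went from 2.09 ± 0.32 to 43.3 ± 8.96 CPM (SD, n = 2 each; 4.37 ± 0.35 SE, adjusted p = 0.000110). CXCL8, the neutrophil attractant interleukin-8, went from 9.91 ± 4.41 to 118 ± 8.37 (3.58 ± 0.35, adjusted p = 0.000253). PTGS2, the inducible cyclooxygenase, was 5.27-fold higher (2.40 ± 0.37), and ICAM1, a leukocyte adhesion molecule, 4.71-fold higher (2.23 ± 0.29). Interferon-stimulated genes moved the other way: 13 of 26 fell, 2 rose and 11 did not pass (2 higher and 14 lower adjusted over the list alone), with a mean of -0.97 (camera adjusted p = 9.07e-05; adjusted p = 0.332 with an estimated correlation). In this list 8 fell and none rose without DMSO replicate 2, and likewise without RB-1 replicate 1. SAMD9L and SAMD9, neighbouring antiviral genes, were 10.6-fold and 8.29-fold lower, IFIT3 4.52-fold lower (-2.18 ± 0.26) and the RNA sensor RIGI 3.82-fold lower (-1.93 ± 0.36). The 2 that rose, named after their values were seen, were IFI27 (2.28) and BST2 (1.96), a membrane tether of viruses.

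Genes of the integrated stress response rose. Of 30 in the ATF4 list, 17 rose, 1 fell and 12 did not pass (19 higher and 1 lower adjusted over the list alone), with a mean of 0.79 (camera adjusted p = 3.22e-06; adjusted p = 0.332 with an estimated correlation). Leaving out DMSO replicate 1, DMSO replicate 2 and RB-1 replicate 1 gave 9, 9 and 10 higher and none lower. The fall was also lost without RB-1 replicate 2 and with upper-quartile factors, library totals alone, no count filter, DESeq2, limma-voom or the legacy fit. DDIT4, an inhibitor of mTORC1 signalling, was 6.06-fold higher (2.6 ± 0.27, adjusted p = 0.000321), PSAT1, of serine synthesis, 3.04-fold (1.60 ± 0.27), CEBPB 2.79-fold (1.48 ± 0.24) and ASNS, asparagine synthetase, 2.46-fold (1.30 ± 0.23). The hypoxia and glycolysis list had 12 of 24 higher, 1 lower and 11 that did not pass (14 higher and 1 lower adjusted over the list alone), with a mean of 0.82 (camera adjusted p = 2.12e-05; adjusted p = 0.332 with an estimated correlation). VEGFA, the angiogenic growth factor, was 4.71-fold higher (2.24 ± 0.25, adjusted p = 0.000421), the glycolytic enzyme gene PGK1 3.63-fold (1.86 ± 0.25), BNIP3, of mitophagy, 3.39-fold (1.76 ± 0.24) and NDRG1 2.36-fold (1.24 ± 0.22). NRF2 targets, which serve antioxidant defence, rose as a list with 4 of 21 higher, none lower and 17 that did not pass (the same numbers adjusted over the list alone; mean 0.53, camera adjusted p = 0.00478; adjusted p = 0.407 with an estimated correlation). Upper-quartile factors gave 8 higher, library totals alone 7, and leaving out DMSO replicate 2 gave 2. Among all 13612 tested genes 1737 were higher. The 4 NRF2 targets that rose were TALDO1 (1.41 ± 0.28), GCLM (1.14 ± 0.25), TXN (1.12 ± 0.30) and TXNRD1 (1.01 ± 0.22). GCLM (1.01, adjusted p = 0.0851) and TXN (1.04, adjusted p = 0.0955) did not pass without DMSO replicate 2, nor did TXN (0.58, adjusted p = 0.163) and TXNRD1 (0.96, adjusted p = 0.0520) without RB-1 replicate 1.

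The heat shock and the ribosome biogenesis lists fell. Of 16 heat shock genes 10 fell, 1 rose and 5 did not pass (the same numbers adjusted over the list alone), with a mean of -1.01 (camera adjusted p = 6.07e-05; adjusted p = 0.332 with an estimated correlation). None rose without DMSO replicate 2 or RB-1 replicate 1, where 7 and 8 fell, nor with no count filter, the legacy fit or the length and GC correction, and 6 fell with library totals alone. HSP90AA1, the inducible cytosolic HSP90, went from 3179 ± 816 to 356 ± 11.2 CPM (SD, n = 2 each; -3.16 ± 0.26 SE, adjusted p = 0.000141), and the list members HSPH1, CHORDC1 and DNAJA1 were 7.32-fold, 5.99-fold and 3.89-fold lower. HSPA1A and HSPA1B, named outside the rule, near-identical copies that fell by 0.82 and 0.80 on the log2 scale, are uncertain because their reads cannot be assigned with confidence. In the ribosome biogenesis and MYC target list 12 of 28 fell, none rose and 16 did not pass (12 lower adjusted over the list alone), with a mean of -0.58 (camera adjusted p = 0.00248; adjusted p = 0.407 with an estimated correlation). Leaving out DMSO replicate 1 gave 7 lower, and DMSO replicate 2 gave 5 lower and 1 higher. UTP20 and HEATR1, of the small-subunit processome, were 13.1-fold and 6.17-fold lower, with HEATR1 uncertain because 23.2% of its exon bases overlap LGALS8 on the opposite strand, and the nucleolar proteins NOP58 and NCL 2.81-fold and 2.68-fold lower.

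Nuclear genes of oxidative phosphorylation and lysosomal genes rose as lists in camera with the preset correlation. Of 26 oxidative phosphorylation genes 11 rose, none fell and 15 did not pass (14 higher adjusted over the list alone), with a mean of 0.70 (camera adjusted p = 0.000181; adjusted p = 0.604 with an estimated correlation). Those that rose numbered 2 without DMSO replicate 2, and 3 with a mean of 0.43 without RB-1 replicate 1. COX5B was 3.22-fold higher (1.69 ± 0.33, adjusted p = 0.00593), COX6C 2.59-fold (1.37 ± 0.27), NDUFB5 2.29-fold (1.20 ± 0.27) and NDUFB8, which shares exon bases with neighbouring genes, 2.67-fold (1.42 ± 0.34). NDUFB5 did not pass without DMSO replicate 1 (1.29, adjusted p = 0.0502) or DMSO replicate 2 (1.13, adjusted p = 0.0930), nor NDUFB8 without DMSO replicate 2 (1.28, adjusted p = 0.0746) or RB-1 replicate 1 (0.84, adjusted p = 0.0793). Mitochondrially encoded genes took 8.68% and 21.7% of the counts in DMSO replicates 1 and 2, and 4.25% and 6.46% in the RB-1 libraries. In the lysosome and autophagy list 4 of 31 rose, 1 fell and 26 did not pass (the same numbers adjusted over the list alone; mean 0.31, camera adjusted p = 0.0316; adjusted p = 0.407 with an estimated correlation), led by the lysosomal protein genes CTSB (1.31 ± 0.24) and PSAP (1.18 ± 0.23). GAA (1.0 ± 0.25) and HEXA (0.98 ± 0.27) did not pass without DMSO replicate 1 (0.93 and 0.95, adjusted p = 0.111 and 0.115) or DMSO replicate 2 (1.08 and 1.04, adjusted p = 0.0816 and 0.104), nor HEXA without RB-1 replicate 1 (0.67, adjusted p = 0.118). The 4 of 31 that rose were near the share among all tested genes, 1737 of 13612. The lysosome list had 8 higher and 1 lower with upper-quartile factors, 9 and 0 with library totals alone, and 10 and 3 with a correction for length and GC content. In the list 2 rose without DMSO replicate 1, and 2 rose and none fell without DMSO replicate 2. The lysosome list itself did not pass without DMSO replicate 1 (adjusted p = 0.0708) or RB-1 replicate 1 (adjusted p = 0.0591).

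**Figure D2:**
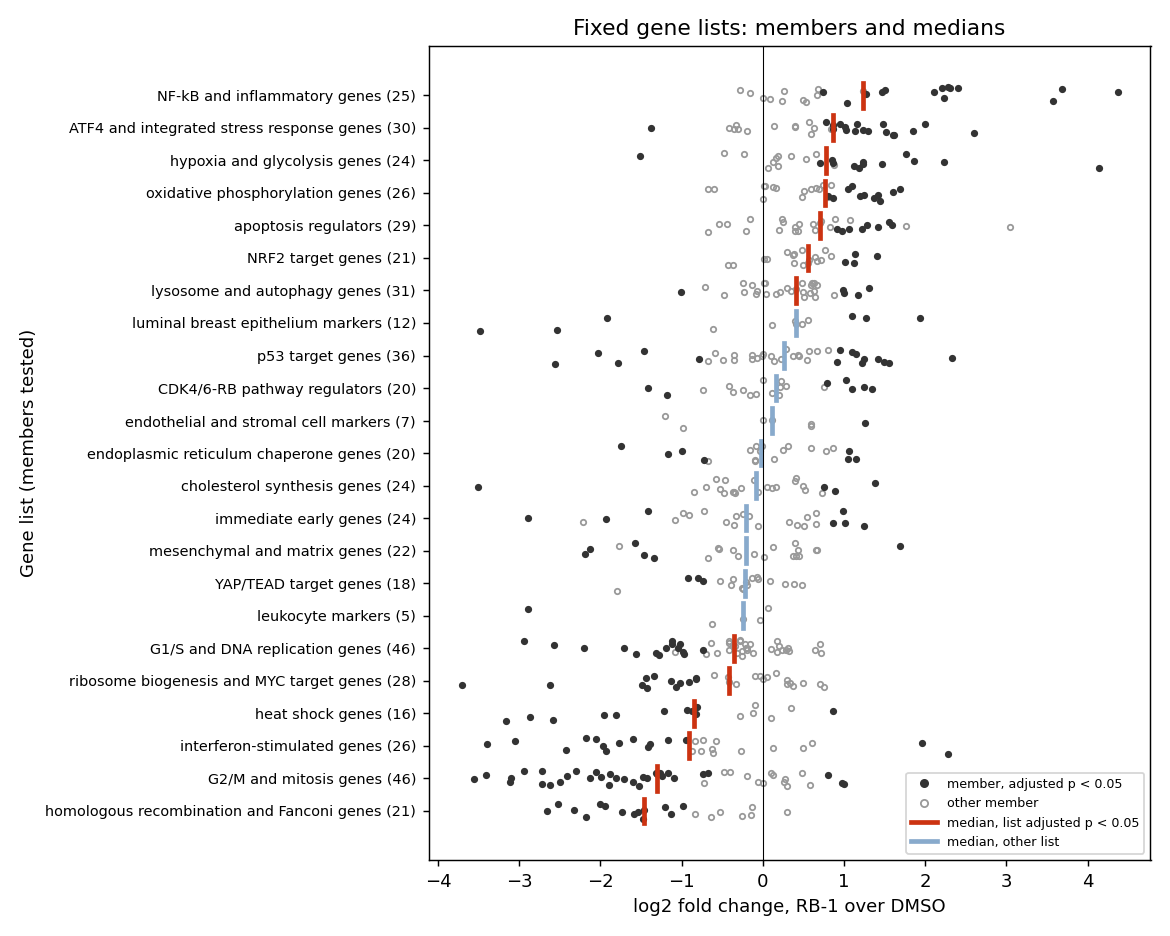
Log2 fold change (RB-1 over DMSO) of every tested member of 23 gene lists fixed before the data were examined, with filled points for members at an adjusted p under 0.05, open points for the others and a bar at the list's median, red where the list passed camera with a preset correlation. CCL20 is drawn at its lower bound, and the medians run from -1.46 for homologous recombination genes to 1.24 for inflammatory genes.

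The remaining lists did not pass camera. Endoplasmic reticulum chaperone genes had 3 higher and 4 lower of 20 (4 and 5 adjusted over the list alone; camera adjusted p = 0.846, mean 0.02 and median -0.03), with HSP90B1 3.36-fold lower. Cholesterol synthesis genes had 3 higher and 1 lower of 24 (2 and 1 adjusted over the list alone; camera adjusted p = 0.943). Mesenchymal and matrix genes had 1 higher and 5 lower of 22 (2 and 6 adjusted over the list alone; camera adjusted p = 0.399), with the matrix glycoprotein gene THBS1 4.37-fold lower. YAP/TEAD targets had 0 higher and 3 lower of 18 (0 and 1 adjusted over the list alone; camera adjusted p = 0.399), led by CRIM1 (-0.92 ± 0.22, adjusted p = 0.0131). Immediate early genes had 4 higher and 3 lower of 24 (the same numbers adjusted over the list alone; camera adjusted p = 0.846), with IER3 2.37-fold higher (1.25 ± 0.28, adjusted p = 0.00996). The test ranked the immediate early list upwards while its mean was -0.27 and its median -0.21. The counts of these lists changed with the scaling and when libraries were left out. With library totals alone there were 4 higher and 1 lower endoplasmic reticulum chaperone genes, 0 and 0 YAP/TEAD targets, 2 and 5 mesenchymal genes and 6 and 1 immediate early genes. The first 3 of these lists stood at 4 and 2, 0 and 1, and 2 and 5 with upper-quartile factors, and at 5 and 3, 1 and 1, and 3 and 6 with the length and GC correction. The correction also gave 3 higher and 2 lower cholesterol genes and 3 and 5 immediate early genes. Immediate early genes had 3 and 0 with limma-voom, 4 and 0 with no count filter and 4 and 1 with a stricter filter, and DESeq2 gave 2 and 5 mesenchymal genes. Without DMSO replicate 2 there were 0 higher and 1 lower endoplasmic reticulum chaperone genes, 0 and 1 cholesterol genes, 1 and 3 mesenchymal genes and 2 and 0 immediate early genes. Without DMSO replicate 1 these were 1 and 1, 0 and 2, 1 and 5, and 0 and 6. Without RB-1 replicate 1 they were 3 and 1, 1 and 1, 1 and 3, and 0 and 0, and without RB-1 replicate 2 they were 4 and 3, 3 and 3, 1 and 4, and 3 and 0. No YAP/TEAD target passed without DMSO replicate 1, DMSO replicate 2 or RB-1 replicate 1. CRIM1 did not pass with library totals alone (-0.73, adjusted p = 0.0505), without DMSO replicate 1 (-0.88, adjusted p = 0.0591), DMSO replicate 2 (-0.94, adjusted p = 0.0571) or RB-1 replicate 1 (-0.81, adjusted p = 0.0846), nor IER3 without DMSO replicate 1 (0.90, adjusted p = 0.0719) or RB-1 replicate 1 (1.19, adjusted p = 0.0774).

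Markers of other cell types were mixed. Of 12 luminal epithelium markers 3 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.851, mean -0.19 and median 0.40 with the test upwards), the fall led by FOXA1, a transcription factor of luminal cells, at 7.32 ± 0.011 CPM in DMSO and 0.652 ± 0.060 in RB-1 (SD, n = 2 each; -3.48 ± 0.38 SE, adjusted p = 0.000379). The luminal list had 1 higher each and 3, 2, 1 and 3 lower without DMSO replicate 1, DMSO replicate 2, RB-1 replicate 1 and RB-1 replicate 2. Of 5 leukocyte markers tested 1 was lower (0 adjusted over the list alone; camera adjusted p = 0.438), PTPRC, with 22 and 13 counts in DMSO and 5 and 0 in RB-1 (-2.89 ± 0.97, adjusted p = 0.0469). PTPRC did not pass with upper-quartile factors, library totals, no count filter, the legacy fit or DESeq2 (adjusted p = 0.0534 to 0.134). It also did not pass without DMSO replicate 1 (-2.52, adjusted p = 0.146), DMSO replicate 2 (-3.16, adjusted p = 0.0582) or RB-1 replicate 2 (-1.93, adjusted p = 0.141). Of 7 endothelial and stromal markers 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.846), ACTA2 (1.26 ± 0.38, adjusted p = 0.0308), 12.8% of whose exon bases overlap FAS on the opposite strand. ACTA2 did not pass without DMSO replicate 1 (0.90, adjusted p = 0.236), RB-1 replicate 1 (1.30, adjusted p = 0.0967) or RB-1 replicate 2 (1.22, adjusted p = 0.0803).

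Among genes with a mean of at least 100 counts, the largest falls included transcripts that were absent from both RB-1 libraries. SPANXA1 and SPANXA2, near-identical sperm-associated genes whose reads are hard to tell apart, had 412 and 370, and 392 and 368 counts in DMSO and 0 in RB-1, which makes them at least 290-fold and 282-fold lower against a floor of 3 counts over the group. AMOT, which encodes the YAP-binding protein angiomotin, had 356 and 237 counts in DMSO and 0 in RB-1, at least 220-fold lower (adjusted p = 0.000124). ZNF521, a zinc-finger transcription factor, had 777 and 660 counts against 0 and 5 (-8.24 ± 0.65), and TFAP2C, the transcription factor AP-2 gamma, 191 and 242 against 4 and 2 (-6.27 ± 0.54). SORL1, a sorting receptor, and PPFIBP2 were 68.3-fold and 66.7-fold lower. The largest rises beside IL1B and CXCL8 were the acute phase gene SAA1 (3.85 ± 0.55, adjusted p = 0.00147), PHETA2 (3.65 ± 0.44) and BEST1 (3.47 ± 0.48), of which BEST1 shares 14.2% of its exon bases with FTH1 on the opposite strand. ATP6V1G2-DDX39B (at least 1566-fold higher), PTGES3L-AARSD1 (34.4-fold higher), ZNF8-ERVK3-1 (22.0-fold higher) and CORO7-PAM16 (101-fold lower) join neighbouring genes and share 100%, 96.0%, 65.4% and 100% of their exon bases with them on the same strand, so their values are uncertain.

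Fold changes followed transcript length. In the quartile of genes with the shortest transcripts 789 were higher and 190 lower, and in the quartile with the longest 189 were higher and 1045 lower, with median log2 fold changes of 0.45 and -0.44. Across 13454 genes, which are not independent replicates, Spearman's correlation of the fold change with length was -0.361, and that of the difference between the RB-1 libraries, replicate 2 minus replicate 1, was 0.399. With a correction for length and GC content, chosen after seeing the data, 2256 genes were higher and 2111 lower, and CDKN1A (0.96, adjusted p = 0.0586), CDK4 (0.64, adjusted p = 0.0663), CDK6 (-0.69, adjusted p = 0.152), CCNA2 (-0.30, adjusted p = 0.224), CRIM1, IER3, NDUFB8, TXN, PTPRC, ACTA2 and the lysosome list (adjusted p = 0.116) no longer passed. The G2/M list then had a mean of -0.92 with 31 of 46 lower, the homologous recombination list -0.86, and the oxidative phosphorylation list 0.50 with 7 higher and 2 lower.

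**Figure D3:**
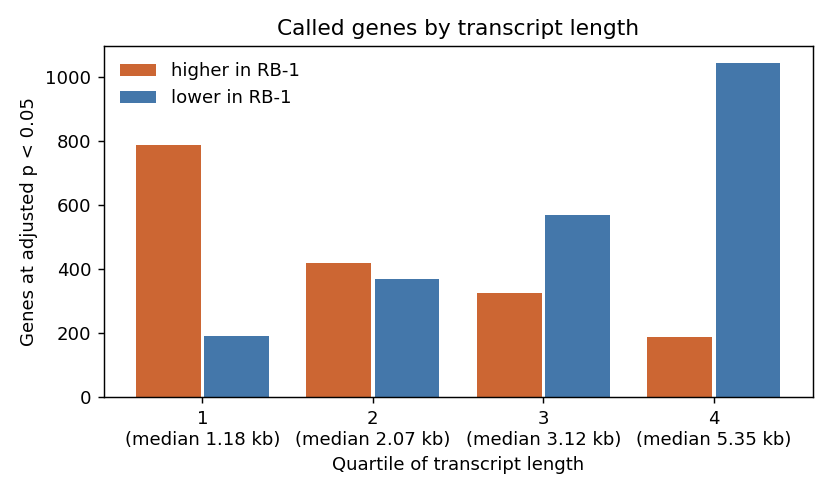
Number of genes at an adjusted p under 0.05 that were higher (orange) or lower (blue) in RB-1, in each quartile of the tested genes by transcript length. The shortest quartile holds 789 higher and 190 lower genes and the longest 189 higher and 1045 lower.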

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

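The length and GC correction, the fit without joined genes and the crossed pairing were chosen after seeing the data. No named gene or list that passed changed direction in any setting, and no gene was called in the opposite direction, the crossed pairing not being examined for these. Leaving out a library ended the call in 36 of 344 values of named genes, in 17 of the 86 genes, and the other settings 23 of 1028, in 10 genes. Of the 86 named genes 80 had a call to lose, and most were picked for a small p or a large change. These shares therefore do not describe all called genes. Of all 3926 called genes, 3135 kept the call with library totals alone and 2992 with the length and GC correction. Depth sets the floor of 3 counts for genes at 0 in a group, and other limits of depth were not tested. With 1 library left in a group, its spread is assumed to be that of the other group.

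Counts of called genes moved as follows, and the cause was not tested except where a stricter threshold set it. Leaving out 1 library gave 1720 to 4398 genes changed, 522 to 1955 higher and 1065 to 2443 lower. An adjusted p under 0.01 left 1580 changed, 513 higher and 1067 lower; testing against a 1.5-fold change left 1884, 651 and 1233. Library totals alone gave 1400 lower. Gene lists past the threshold were 0 with an estimated correlation and 8 with fry (7 of the main 13, and the YAP/TEAD list).

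Some values that had not passed changed sign. MDM2 was at 0.094 with upper-quartile factors, 0.24 with library totals, and from -1.77 to 0.75 leaving out a library, passing at -1.77 without RB-1 replicate 2. Leaving out a library also moved CCNB1 from -0.15 to 0.31, E2F1 from -0.19 to 0.57, the cholesterol list mean from -0.22 to 0.043, the immediate early list from -0.57 to 0.20, the luminal list from -0.40 to -0.25 (the test's direction changed) and the endothelial and stromal list from -0.34 to 0.30. The cholesterol list was at 0.094 with library totals. With the length and GC correction CCND1 was at -0.072 and E2F1 at -0.011, and the direction of the test, not the sign of the mean, changed for the immediate early (-0.37) and luminal (-0.27) lists.

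The labels give both groups replicate numbers 1 and 2 and no shared culture or day, and same-numbered libraries did not deviate together (Pearson -0.0959 and Spearman -0.139 across 13612 genes), so the numbers are not taken to pair the libraries. The replicate block gave 4055 genes changed, 1741 higher and 2314 lower; of the named genes, CCNA2 did not pass (adjusted p = 0.0528), MYC passed (1.03, adjusted p = 0.0486) and no other call changed. The block called 11 of the 13 mitochondrially encoded genes lower, against 4, and 0 genes of the ATF4 list lower, against 1. The crossed pairing, tried because the measures fell on either side of -0.1, gave 4520, 1970 and 2550.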

Other observations

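Of the tests below, those of the trend within a group, of the marker lists, of X-linkage, of the genomic span of the lost genes and of the mitochondrial share were chosen after the results were seen. Genes of cytosolic ribosomal proteins, a class not among the fixed lists, were mostly higher in RB-1: of 82 tested, 46 rose and 2, RPL6 and RPL23A, named after their values were seen, fell, with a median log2 fold change of 0.91 that stayed above 0 under every scaling tried (0.90 to 1.10). They took 3.45% and 2.61% of the counts in DMSO and 6.75% and 4.76% in RB-1. Their median ran from 0.59 without RB-1 replicate 1 to 1.15 without RB-1 replicate 2 when a library was left out. The length and GC correction left 28 higher and 6 lower with a median of 0.44, and 14 were higher without DMSO replicate 2 and 15 without RB-1 replicate 1.

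Some further members of the lists that did not pass are named here after their values were seen. The 5 members of the CDK4/6-RB list that rose were CDK4 and the genes of the inhibitors CDKN1A, CDKN2D (1.35), CDKN1C (1.10) and CDKN1B (0.79), while CDKN2C did not pass (adjusted p = 0.999); none of the 5 passed without DMSO replicate 2 or without RB-1 replicate 1. Among p53 targets the rises included GDF15 (2.33), the death-promoting BBC3 (1.42), PHLDA3 (1.5) and GADD45A (1.15), and the falls CYFIP2 (-2.03), TIGAR (-1.79), CCNG1 (-1.47) and PLK2 (-0.78). The 5 of 22 mesenchymal and matrix genes that fell were THBS1, ZEB1 (-2.18), SNAI2 (-1.57), TGFB2 (-1.46) and ZEB2 (-1.34), and 3 genes of the list fell without DMSO replicate 2 or without RB-1 replicate 1.

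The fall of long and rise of short transcripts may be partly a property of the libraries, since the 2 RB-1 libraries differed from each other along length with a Spearman correlation of 0.399, larger in size than the -0.361 of the treatment, although the DMSO libraries differed by -0.0857; with GC content the correlations were 0.303 for the treatment, 0.316 within DMSO and -0.506 within RB-1. With the correction the mean of the lower G2/M list went from -1.23 to -0.92, with 31 of 46 genes lower. The trend, as far as the correction models it, therefore does not account for the whole fall. The camera adjusted p of 1.62e-13 then, with the preset correlation, treats the genes as nearly independent. The estimated correlation of the G2/M genes was 0.145, so this p adds no decision. Before the correction the camera adjusted p of the G2/M list with an estimated correlation was 0.332. The mean of the higher oxidative phosphorylation list went from 0.70 to 0.50 (camera adjusted p = 0.0136, preset correlation), with 7 genes higher and 2 lower. That test cannot decide for this list, because it treats the genes as nearly independent. Their estimated correlation was 0.65, and camera with it gave an adjusted p of 0.604 before the correction. A biological candidate is that genes with a long genomic span lose output after RB-1: given transcript length and GC content, the partial Spearman correlation with span was -0.139 (95% bootstrap interval -0.157 to -0.122 over 13454 genes). The interval comes from resampling genes and holds no spread between libraries. The partial correlations with transcript length, given span and GC content, and with GC content, given length and span, were larger in size, at -0.239 and 0.194. The value of -0.139 lies between the bounds set beforehand for and against the candidate, -0.2 and -0.1. A loss in long genes and a bias of the libraries therefore cannot be told apart for this trend. The correction removes a true trend along length together with a false one.

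More transcripts vanished than appeared: 23 genes had at least 30 counts in both DMSO libraries and at most 3 in both RB-1 libraries, among them AMOT, POF1B, STXBP6, TENM1 and DSCAM, against 3 genes the other way (ATP6V1G2-DDX39B, TSPOAP1 and 1 without a symbol), limits and names being chosen after the values were seen. The 244 other tested genes within 1 Mb had a median log2 fold change of -0.0878 (quartiles -0.881 and 0.535). This argues against loss of a chromosome segment of that size around most of the 23. The neighbours were pooled, so loss around a few of the genes or of a shorter segment is not excluded. Of the 23, 6 are X-linked against 3.18% of tested genes (Fisher's exact test, two-sided, p = 6.33e-05, SPANXA1 and SPANXA2 counted apart). The 426 other tested X-linked genes had a median of -0.0658. Cells of another type in the DMSO cultures stay open: at most 25% of the tested members of the luminal, leukocyte and stromal lists were lower, but only 5 of 16 leukocyte markers could be tested, too few for that test to exclude them, and CD33, a myeloid gene, is among the 23. The genes had a median genomic span of 198.3 kb against 26.2 kb in 10000 random sets matched on DMSO level (percentile 100). A loss of output from long genes is therefore a candidate explanation for those among them with a long span. It is not one for the short genes among them, such as SPANXA1 and SPANXA2, the shortest at 1.3 kb. A difference in the cell stock behind the groups was not tested and stays open.

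Mitochondrially encoded transcripts and nuclear oxidative phosphorylation transcripts moved apart: the 13 mitochondrial genes had a median log2 fold change of -1.77, with 4 called lower and none higher, while 11 of 26 nuclear genes rose, or 2 and 3 without DMSO replicate 2 and RB-1 replicate 1. DMSO replicate 2 had a mitochondrial share of 21.7%, against 8.68% in DMSO replicate 1. The mitochondrial calls numbered 13 without DMSO replicate 1, 0 without RB-1 replicate 1 or RB-1 replicate 2, 11 with DESeq2, 9 with the legacy fit, 2 with upper-quartile factors, and 1 with limma-voom, no count filter or the length and GC correction. Without DMSO replicate 2 the median was -0.83 with 3 called, and the difference between the RB-1 libraries, 4.25% and 6.46%, is too large beside that for 1 remaining DMSO library to decide. Whether the high share of 1 library or an effect of RB-1 is behind the lower level therefore cannot be told apart.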
